A study of Mus musculus with 2 samples.

How the data were processed

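Single-cell RNA sequencing had been made from 4T1 tumours of mice given normal saline or beta-elemene, with 1 library per group. Per the labels' protocols, tumours were dissociated with an enzyme kit, passed through a 40-µm strainer, treated to lyse red blood cells and loaded on a droplet instrument with 3' chemistry, version 3. The deposited values are counts, as unnormalised UMI counts per gene and barcode. Per the file headers the matrices were written by Cell Ranger 7.1.0, and per the submitters' processing notes reads were aligned with Cell Ranger and STAR to the mm10 build. The annotation release, the counting of intron reads and the rule that called cells are not stated. Each file lists 32285 genes, and the lowest count of any deposited barcode was 500 UMIs in both libraries. Mitochondrial genes held 4.11% of UMIs in vehicle and 4.28% in beta-elemene, and the ribosomal-RNA-like gene Gm42418 held 5.24% and 4.67%.

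Barcodes were kept with at least 200 detected genes and at most 20% mitochondrial UMIs. In vehicle 52 barcodes fell under the gene minimum and 520 over the mitochondrial limit, and in beta-elemene 157 and 674, leaving 10803 and 10861. Doublets were called in each library by comparison with simulated doublets, with an automatic threshold, and 357 (3.30%) and 312 (2.87%) were removed. Genes seen in at least 3 cells were kept. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together, without batch correction, on 2000 variable genes chosen with the library as a batch key, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0, with sub-clusters at 0.6. Clusters were named from fixed marker lists, with at least 3 markers detected, and clusters without a clear best class were left unnamed. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, umap-learn 0.5.12 and matplotlib 3.10.9.

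Shares of kept cells were given with exact binomial intervals and their differences with 95% intervals. Within each class UMIs were summed per library and scaled to a common total of each class (CPM), and the ratio of beta-elemene to vehicle was given with an exact Poisson interval. Classes with at least 100 cells in each library were compared, which left 8. Both kinds of interval cover counting error only. No test, p-value or standard error was made from cells, because cells of 1 library are not replicates. Median UMIs per cell in vehicle and beta-elemene were 20038.5 and 20471.5 for malignant cells, 1922.5 and 1979 for neutrophils, 12605.5 and 11398 for macrophages, and 6959.5 and 7020 for monocytes. They were 4046 and 4402 for T and natural killer cells, 6818.5 and 7227 for dendritic cells, 20770 and 21829 for fibroblasts, and 9246.5 and 8983 for endothelial cells.

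Genes were named by a fixed rule of size. A gene needed at least 100 UMIs in both sums together, an interval that excluded 1, and, in the library where it was higher, a UMI in at least 5% of the class's cells and at least 20% of the CPM of the class where it was highest. Of these the 12 highest and 12 lowest ratios were named in classes with at least 500 cells in both libraries, and the 5 highest and 5 lowest in the others, 164 in all. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment genes and unnamed gene models were not eligible. Genes cited beside gene lists were the most abundant and the most extreme members. The 44 gene lists were written by hand. A list was measured in a class if at least 5 members had at least 50 UMIs, and its median log2 ratio was placed among those of 10000 random lists matched on expression in 50 bins. A member was called higher or lower if its ratio was at least 1.5-fold and its interval excluded 1. Random lists describe these libraries and do not replace replicates. Positions and transcript lengths came from GENCODE vM21, which matched 99.6% of genes.

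The procedure was tested on simulated data, in which counts of each class were redrawn with 200 changed genes. The intervals covered the true ratio for 95.1% to 96.1% of genes. The interval excluded 1 for 98.5% to 100% of genes raised 2-fold, 93.9% to 100% of those lowered to 0.5 and 82.1% to 98.5% of those raised 1.5-fold. Of 800 unchanged lists 7 lay outside the middle 99%. The counts were drawn as Poisson sums, which the intervals assume, so the coverage checks the calculation only. It does not cover UMIs concentrated in single cells. The unchanged lists were random genes, so they do not show how lists of genes that vary together behave.

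Alternatives for shares were resolutions 0.5 and 2.0, each library clustered alone, doublets kept, at least 500 genes with at most 10% mitochondrial UMIs, every deposited barcode, cells thinned to 1000 UMIs, and immune cells alone. For ratios and lists they were other scalings, the mean over cells, a pseudocount of 10 CPM, other UMI minimums, subtraction of free RNA, the largest sub-cluster, and the mean or sum of a list in place of its median. Alternatives without clusters of low depth, without clusters with over 90% of cells from 1 library, centred by transcript length, and without the cell holding most UMIs of a gene were added later. Pericytes, natural killer cells and rarer sub-types were too few to compare gene by gene, and reads were not realigned.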

Results

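Single-cell RNA sequencing was used to compare 4T1 tumours from mice given beta-elemene with 4T1 tumours from mice given saline. The 4T1 line is a mouse model of triple-negative breast cancer, and beta-elemene is a plant sesquiterpene. The tumours grew in the mammary fat pad, and the drug was injected into the abdomen daily at 30 mg/kg for 18 days. The question stated in the series title was how beta-elemene acts on the immune and metabolic state of these tumours. Each group was 1 library made with 3' droplet chemistry, and the labels do not state how many mice went into it. The difference between the groups therefore has no replicate check, and no test was made. The vehicle library held 11324 barcodes with 168750895 unique molecular identifiers (UMIs), a median of 11878.5 UMIs and 3177 genes per barcode. The beta-elemene library held 11539 barcodes with 157282740 UMIs, a median of 9682 UMIs and 2773 genes. Filters and the removal of called doublets left 10446 vehicle cells and 10549 beta-elemene cells. Ratios are beta-elemene over vehicle throughout, and intervals are exact 95% intervals that cover counting error only. Class names come from clusters rebuilt here and named from fixed markers, so each class is to be read as malignant-like, neutrophil-like and so on.

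The beta-elemene tumour library held fewer malignant cells and more neutrophils than the vehicle library. Malignant cells made up 40.1% of vehicle cells (39.2 to 41.1) and 32.5% of beta-elemene cells (31.6 to 33.4), a difference of -7.58 percentage points. Neutrophils, short-lived phagocytes that tumours can recruit in large numbers, made up 10.7% of vehicle cells (10.2 to 11.4) and 16.8% of beta-elemene cells (16.1 to 17.6), a ratio of 1.57. All immune classes together went from 50.6% to 58.7% of cells. Macrophages, the most common immune class, had close shares of 27.6% and 28.3%, and their difference of 0.726 points had an interval from -0.495 to 1.95. Monocytes, the blood-borne precursors of many tumour macrophages, made up 5.0% and 5.83%. T and natural killer cells made up 5.56% and 6.03%, the dendritic cluster, which also held mast and B cells, 1.67% and 1.70%, fibroblasts 6.23% and 6.06%, and endothelial cells 1.84% and 1.79%, and the interval of each of these 4 differences included 0. Pericytes made up 0.383% and 0.360%. Clusters left without a name held 0.881% and 0.559% of cells. Most of the malignant difference lay in a pair of clusters, one of 1053 vehicle and 694 beta-elemene cells and one of 745 and 465, while the most common malignant cluster went the other way with 1081 and 1246. A pair of malignant clusters came almost wholly from the vehicle library, with 177 and 8 cells in one and 83 and 3 in the other, and such clusters can mark the library in place of a cell type. The neutrophil difference was 3.38 points at a clustering resolution of 2.0, where a shallow cluster of 420 vehicle and 707 beta-elemene cells that scored closest to neutrophils was left unnamed. Where each library was clustered alone the monocyte difference was -3.85 points and the macrophage difference 5.09, and the macrophage difference was -6.33 among immune cells alone and -1.19 without low-depth clusters. Enzymatic dissociation, red cell lysis and the lowest UMI count among the deposited barcodes, 500, can all set shares, above all for neutrophils, whose median was 1922.5 UMIs in vehicle and 1979 in beta-elemene.

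**Figure D1:**
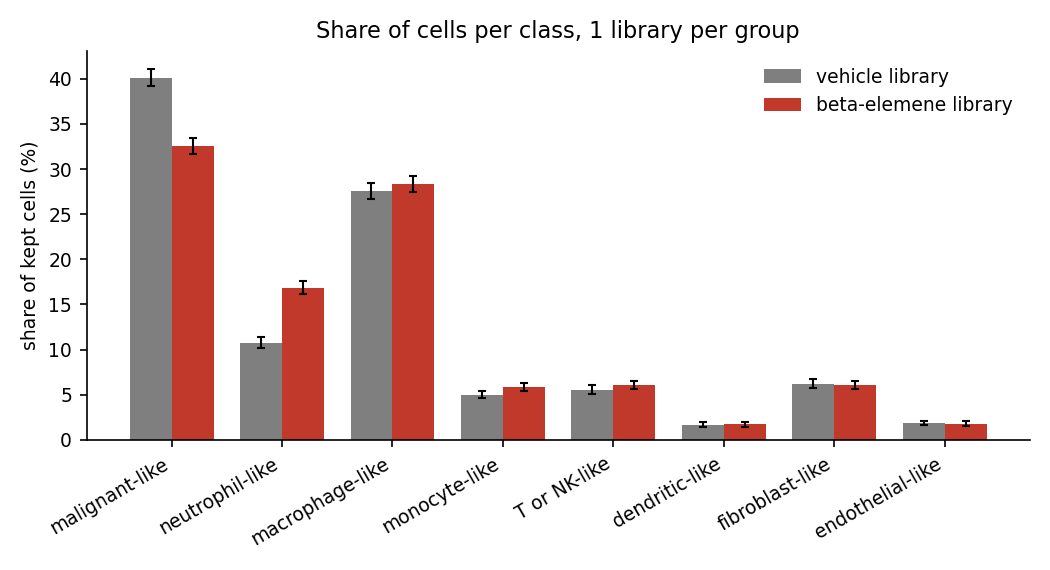
Share of kept cells (%, vertical axis) in each cell class for the vehicle library (grey) and the beta-elemene library (red), 1 library each, with exact 95% intervals for counting error as error bars. Malignant cells were at 40.1% and 32.5%, and neutrophils at 10.7% and 16.8%.

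The list of MHC class I antigen presentation, whose genes display peptides to CD8 T cells, had a higher median with beta-elemene in all 8 compared classes. The median log2 ratio was 0.37 in malignant cells, 0.28 in neutrophils, 0.34 in macrophages, 0.41 in monocytes, 0.17 in T cells, 0.34 in dendritic cells, 0.34 in fibroblasts and 0.50 in endothelial cells. Of its 17 measured genes, at least 14 had a ratio above 1 in every class, and none was at least 1.5-fold lower in any. In endothelial cells 5 genes were at least 1.5-fold higher and 12 were neither, and in neutrophils 4 were higher and 13 were neither. The other counts of higher genes were 2 each in macrophages, monocytes and dendritic cells, 1 each in malignant cells and fibroblasts, and 0 in T cells. H2-D1, a classical class I heavy chain, had ratios from 1.19 in T cells to 1.44 in endothelial cells. Psmb9 (chromosome 17, 34181987 to 34187764), an immunoproteasome subunit that trims peptides for loading, had a ratio of 1.47 in macrophages, 1.67 in monocytes and 1.76 in fibroblasts. H2-T23 (chromosome 17, 36029773 to 36032855), the non-classical Qa-1 molecule, had a ratio of 1.72 (1.66 to 1.78) in malignant cells and 1.71 (1.61 to 1.81) in macrophages. Coordinates are on the mm10 build. Reads of H2 genes can be shared between near-identical copies, so values of single H2 genes are uncertain. Within the largest sub-cluster alone the list's median was 0.19 in malignant cells and 0.18 in macrophages.

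The median of the interferon gamma list was also higher in most classes. That of the type I list was above 0 in most classes too, but only 4 of them met the limits for description given below. The interferon gamma list had a median log2 ratio of 0.47 in monocytes, 0.42 in endothelial cells, 0.38 in dendritic cells, 0.33 in neutrophils, 0.21 in macrophages and 0.19 in malignant cells. At least 1.5-fold higher were 4 of 22 measured genes in monocytes, 6 of 20 in endothelial cells, 5 of 17 in dendritic cells, 5 of 18 in neutrophils, 0 of 22 in macrophages and 0 of 23 in malignant cells. None was at least 1.5-fold lower except Ido1, a tryptophan-degrading enzyme, in malignant cells at 0.584 (0.709 with the cell holding most of its UMIs left out). In T cells its median was 0.06, inside the range of random lists, and in fibroblasts it was 0.39 at under 20% of the level of the highest class. The type I interferon list was highest in endothelial cells at 0.64, with 10 of 20 genes higher, none lower and 10 neither. It stood at 0.40 in monocytes, 0.31 in fibroblasts and 0.21 in neutrophils, while macrophages had 0.09, malignant cells 0.08, T cells -0.04 and dendritic cells -0.14. These 4 were not described. Isg15, a ubiquitin-like protein made in answer to interferon, had a ratio of 2.07 in monocytes, 1.13 in their largest sub-cluster, and 1.55 in neutrophils. Bst2, or tetherin, which holds budding viruses at the cell surface, had a ratio of 1.67 in fibroblasts and 1.59 in both endothelial cells and macrophages. Within the largest sub-cluster alone, the interferon gamma median was -0.32 in malignant cells and 0.03 in macrophages, and the type I median was 0.05 in neutrophils.

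**Figure D2:**
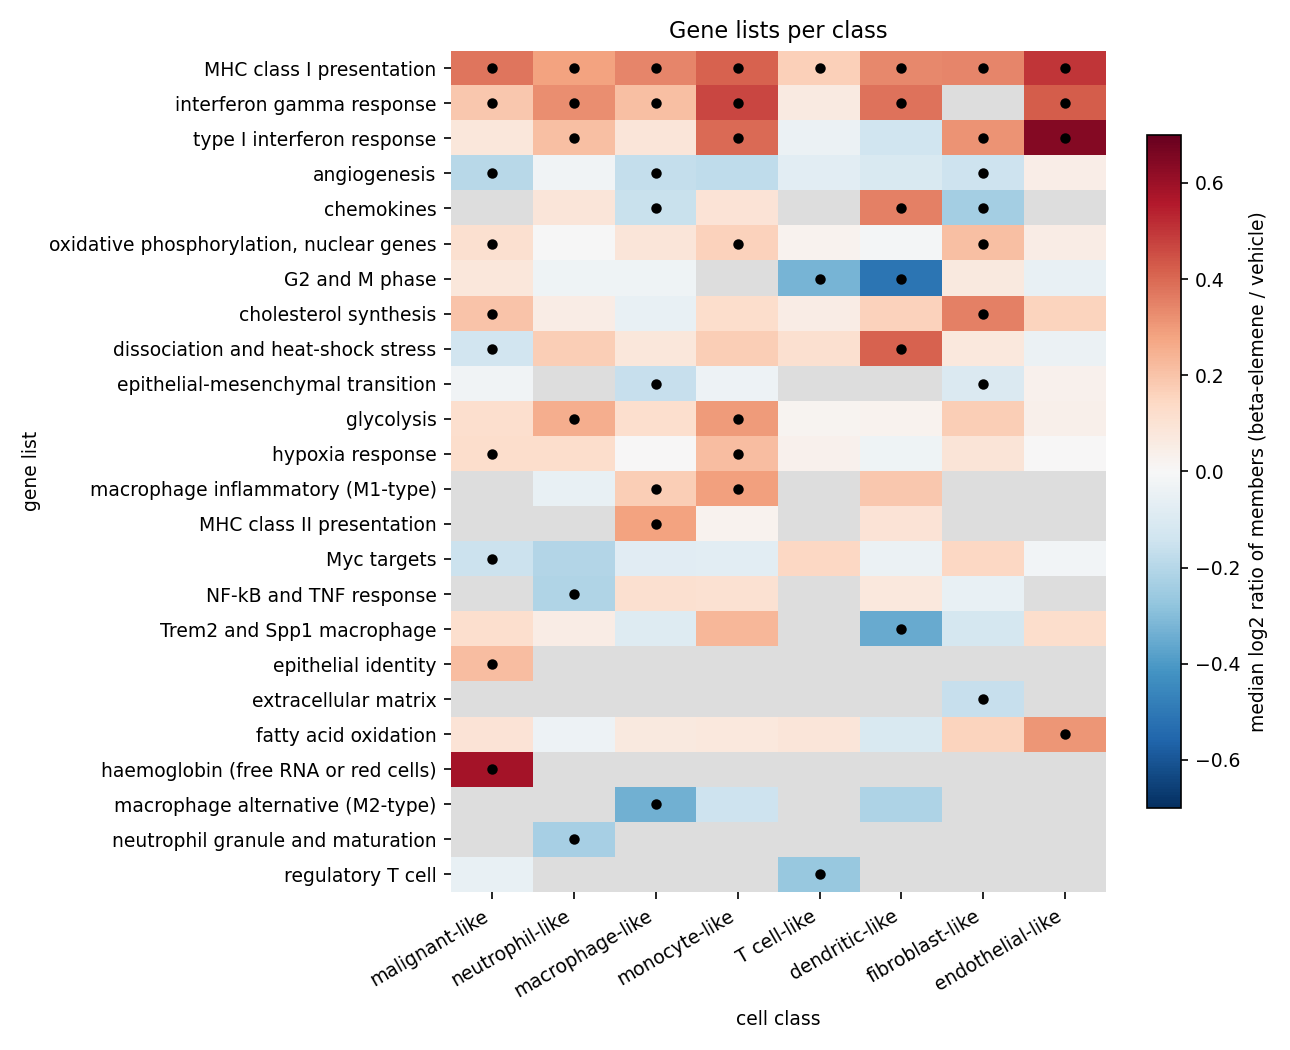
Median log2 ratio of beta-elemene over vehicle (colour, limited to the range from -0.7 to 0.7) for 24 gene lists (vertical axis) in 8 cell classes (horizontal axis), 1 library per group. Black dots mark the lists described in the text, and grey marks lists with under 5 measured genes or under 20% of the level of the highest class. The row of MHC class I presentation was above 0 in every class, from 0.17 in T cells to 0.50 in endothelial cells.

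In malignant cells, the medians of the epithelial and cholesterol synthesis lists were higher with beta-elemene, while those of angiogenesis, Myc targets and the stress response were lower. The highest ratio was that of Wnt6 (chromosome 1, 74771892 to 74785322), a secreted Wnt ligand, at 3.55 (2.94 to 4.30), from 1.59 to 5.66 UMIs scaled to a common class total (CPM). Cxcl5 (chromosome 5, 90759360 to 90761624), a chemokine that attracts neutrophils through Cxcr2, had a ratio of 3.21 (2.80 to 3.69), from 3.05 to 9.80 CPM. Next came Fgfbp1, which frees fibroblast growth factors from the matrix, at 2.0, and Bspry at 1.99. These were followed by the forkhead factor Foxq1 at 1.89, the epithelial clathrin adaptor Ap1m2 at 1.88, the recycling GTPase Rab25 at 1.81 and the polarity protein Crb3 at 1.79. S100a14 stood at 1.79, the serine dehydratase-like gene Sdsl at 1.79 and the kinase gene Hunk at 1.74. The epithelial identity list had a median of 0.21, with 1 of 15 genes at least 1.5-fold higher, none lower and 14 neither. Its most abundant members were the keratins Krt8 at 1.12 and Krt18 at 1.19. Cholesterol synthesis had a median of 0.20, with 20 of 22 genes above a ratio of 1 and none past 1.5-fold either way. This list had a median of 0.086 within the largest sub-cluster and a log2 ratio of 0.27 in summed counts. Among its genes Hmgcs1, an early enzyme of the pathway, stood at 1.40, Fdps at 1.36 and Ebp at 1.34.

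On the lower side in malignant cells stood Tktl1, a transketolase-like gene, at 0.353 (0.297 to 0.417), from 6.49 to 2.29 CPM. Csnk2a2, a catalytic subunit of casein kinase 2, went from 97.1 to 43.2 CPM, a ratio of 0.445 (0.428 to 0.463). The anti-inflammatory cytokine Il10 was at 0.434. The other lower genes of the naming rule were Pbld1 at 0.386, Plet1os at 0.392, Dynap at 0.401, P4htm at 0.411, Ccdc7a at 0.418, the glycine receptor gene Glra1 at 0.448, Ttc23l at 0.456, Nwd1 at 0.469 and Bicdl2 at 0.470. Plet1os lies antisense to Plet1, and its reads may belong to that gene. The angiogenesis list had a median of -0.19, with 2 of 16 genes at least 1.5-fold lower, none higher and 14 neither, and Nrp2, a co-receptor for vascular growth factor, was at 0.874. Myc targets, genes of cell growth, had a median of -0.15 with no gene past 1.5-fold, and included the polyamine enzyme Odc1 at 0.695, Ncl at 0.870 and Npm1 at 1.09. The dissociation and heat-shock list had a median of -0.13, with 1 of 18 genes lower, none higher and 17 neither, and its members included Egr1 at 0.663, Fos at 0.874 and Hspa8 at 0.907. The hypoxia list had a median of 0.12, where 1 of 19 genes was higher, Ankrd37 at 1.53, and 18 were neither, with Ldha at 1.01 and Mif at 1.03. Haemoglobin RNA, which comes from red cells, was higher among malignant cells at a median of 0.58, with 2 of 5 genes higher, none lower and 3 neither. Single cells held much of it, 1832 of the 6115 vehicle and 1602 of the 9106 beta-elemene UMIs of Hbb-bs. Most of the 24 named genes had a low CPM, although each had at least 100 UMIs by the naming rule. With 10 CPM added to both libraries 16 of them moved by over 1.5 times, Wnt6 to 1.35, Cxcl5 to 1.52 and Tktl1 to 0.745. In summed counts the log2 ratio was -0.04 for Myc targets and -0.07 for angiogenesis, and the Myc median was -0.06 in the largest sub-cluster. Without the low-depth clusters the haemoglobin median was 5.46, and within the largest sub-cluster Ldha had a ratio of 0.925.

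**Figure D3:**
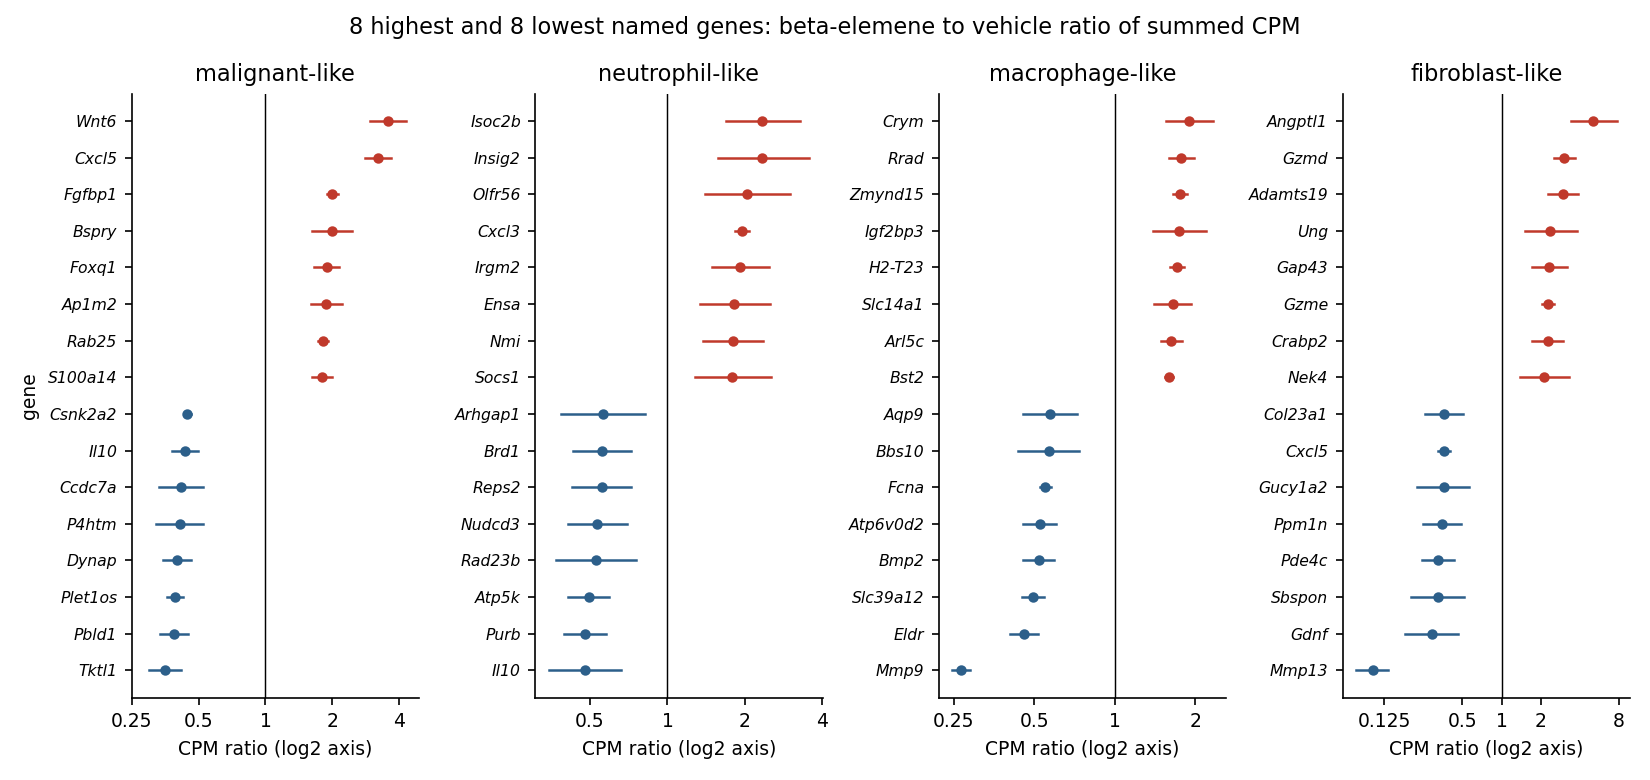
Ratios of beta-elemene over vehicle CPM (horizontal log2 axis, line at 1) of the 8 highest and 8 lowest named genes (vertical axis) in each of malignant cells, neutrophils, macrophages and fibroblasts, 1 library per group. Points are the ratios of summed counts, red for higher and blue for lower, with exact 95% intervals for counting error. In macrophages Mmp9 lies apart at 0.266, and in malignant cells Wnt6 lies at 3.55.

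Neutrophils of the beta-elemene library had higher medians of interferon-response and glycolysis genes. Cxcl3, a neutrophil-attracting chemokine, went from 478 to 931 CPM, a ratio of 1.95 (1.82 to 2.08). The interferon-induced GTPases Irgm2 and Igtp had ratios of 1.92 and 1.73, the interferon-induced adaptor Nmi 1.79, and Socs1, a feedback inhibitor of cytokine signalling, 1.78. Insig2, which holds back sterol synthesis, and Isoc2b were both at 2.33. Olfr56 stood at 2.03, Ensa at 1.82, the vault protein Mvp at 1.73, Olfm4, a granule protein of a neutrophil subset, at 1.66 and Trappc6a at 1.66. Glycolysis genes had a median log2 ratio of 0.25, with 16 of 17 above a ratio of 1 and none past 1.5-fold, among them the glucose transporter Slc2a3 at 1.39 and Gapdh at 1.19. In the type I interferon list 5 of 23 genes were at least 1.5-fold higher, none lower and 18 neither. Il10 was lower at 0.479, from 35.2 to 16.9 CPM, as were Purb at 0.479, Atp5k, a subunit of ATP synthase, at 0.495, and Rad23b at 0.528. The 8 other lower genes were Nudcd3, Reps2, Brd1, Arhgap1, Mrpl52, Slc4a7, Ntng2 and Dctn1, with ratios from 0.534 to 0.585. The transcript of Atp5k is 321.5 nt long, and genes with transcripts up to 400 nt had a median log2 ratio below 0 in every class. The granule and maturation list had a median of -0.24, with 1 of 14 genes higher, none lower and 13 neither, and included Ngp at 0.754 and Retnlg at 1.13. The NF-kB list had a median of -0.21 with none of its 22 genes past 1.5-fold, and included Nfkb1 at 0.689, while the abundant Il1b at 1.23 and Cxcl2 at 1.06 gave its summed counts a log2 ratio of 0.10. Within the largest neutrophil sub-cluster the granule median was 0.39, opposite in sign, and the type I interferon median was 0.05. Igtp had a ratio there of 2.70, Retnlg 1.83 and Reps2 0.333. With free RNA subtracted Rad23b was at 0.27.

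In macrophages the medians of the MHC class II and interferon gamma lists were higher with beta-elemene and that of the M2-type list was lower, and Mmp9 was the gene that differed most. Mmp9 (chromosome 2, 164940780 to 164955850), a gelatinase that cuts matrix collagen, went from 91.4 to 24.3 CPM, a ratio of 0.266 (0.246 to 0.286). Its ratio was 0.505 at a clustering resolution of 0.5, where monocytes and macrophages were not parted. Mmp9 was also a top gene of a macrophage sub-cluster with a smaller share in beta-elemene, described below. Fcna, a lectin of the complement system made by resident macrophages, went from 135 to 74.0 CPM, a ratio of 0.550. Slc39a12 and Slc39a8, both zinc transporters, had ratios of 0.494 and 0.584, and Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, 0.523. The growth factor Bmp2 was at 0.518, the non-coding Eldr at 0.457, or 0.728 in the largest sub-cluster, the glycerol channel Aqp9 at 0.572, the thrombin receptor Thbd at 0.584 and the Mediator kinase Cdk8 at 0.577, with Bbs10 at 0.566 and Zcwpw1 at 0.572. On the higher side were Crym at 1.90, Rrad at 1.77, Zmynd15 at 1.76, Igf2bp3 at 1.74, the urea transporter Slc14a1 at 1.64 and Arl5c at 1.63. Bst2 went from 132 to 211 CPM, a ratio of 1.59, and H2-Q7, Ccdc102a, Dynlt1c and Smco4 had ratios from 1.5 to 1.57.

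MHC class II presentation, through which macrophages and dendritic cells show peptides to CD4 T cells, had a median of 0.28 in macrophages. Of its 12 genes 11 were above a ratio of 1 and none passed 1.5-fold, with Cd74 at 1.35, its transactivator Ciita at 1.43 and Ctss at 1.01. The M2-type list had a median of -0.34, where 1 of 20 genes was at least 1.5-fold lower, none higher and 19 neither, and 17 had a ratio below 1. It included the mannose receptor Mrc1 at 0.788 and the arginine-degrading enzyme Arg1 at 0.826. Ccl22, a chemokine for regulatory T cells, was at 0.284, but 1 vehicle cell held 87 of its 154 vehicle UMIs and the ratio was 0.575 without the highest cells. Its ratio was 0.789 with 10 CPM added and 0.060 with free RNA subtracted. The M1-type list had a median of 0.17, with 1 of 15 genes lower, none higher and 14 neither, and included Il1b at 1.19, Cd86 at 1.15 and Ccr7 at 0.392, the last at 0.699 in the largest sub-cluster, 0.808 with 10 CPM added and 0.224 with free RNA subtracted. Chemokines had a median of -0.16, with 2 of 22 lower, none higher and 20 neither, and angiogenesis genes -0.17, with none of 14 past 1.5-fold. Genes of epithelial-mesenchymal transition had a median of -0.16, with 1 of 19 lower, none higher and 18 neither, and included Fn1 at 0.799, but the median was -0.01 with free RNA subtracted and -0.09 in the largest sub-cluster. Macrophage clusters differed in size between the libraries, a Mmp12 and Arg1 cluster with 1153 cells in vehicle and 902 in beta-elemene, an MHC class II and C1q cluster with 1118 and 1322, and a low-depth cluster with 83 and 259. When macrophages, monocytes and the dendritic cluster were clustered together, a Lyve1 and Cd163 macrophage sub-cluster held 402 cells in vehicle (11.2%, 10.2 to 12.3) and 337 in beta-elemene (8.91%, 8.02 to 9.87). Its top genes included Fcna, Slc39a12 and the M2-type members Cd163, Cbr2 and Folr2. Mmp9, Mmp12 and Arg1 were among the top genes of another macrophage sub-cluster. It held 898 cells in vehicle (25.1%, 23.7 to 26.6) and 718 in beta-elemene (19.0%, 17.8 to 20.3). Whether the smaller share of either sub-cluster accounts for the lower values of its top genes was not tested. Within the largest macrophage sub-cluster the medians were -0.22 for the M2-type list, 0.20 for MHC class II, 0.06 for the M1-type list, 0.04 for chemokines and 0.07 for angiogenesis.

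Monocytes had the highest interferon gamma median among the 8 classes, and 7 lists were described in them, all higher with beta-elemene. Cxcl9 (chromosome 5, 92321347 to 92328079), a chemokine that draws T cells through Cxcr3, went from 51.4 to 117 CPM, a ratio of 2.27 (1.93 to 2.69). Parp10, an interferon-induced ADP-ribosyltransferase, was at 2.23, the granule protease Prtn3 at 2.08, Ly6c1 at 2.08 and the lysozyme Lyz1 at 3.05. Bola1, Mgat4b, Npl, Fgf13, Gmpr2 and Cirbp had ratios from 1.98 to 2.17. The M1-type list had a median of 0.29, with 3 of 13 genes higher, none lower and 10 neither, and included Il1b at 1.43. Glycolysis had a median of 0.30 with no gene past 1.5-fold, among them Gapdh at 1.33, Pkm at 1.37 and Pfkl at 1.40. Hypoxia genes had a median of 0.21, with 2 of 17 higher, among them the oxidase Ero1l at 1.67, and 15 neither, and oxidative phosphorylation 0.16, with 1 of 41 higher, Ndufs3 at 1.52, and 40 neither. Slc39a12 was lower at 0.407 and Cdk8 at 0.557, and the 9 others, Dennd5b, Sclt1, Spata7, Fam20a, Edil3, Akap11, Znrf3, Il31ra and Pola1, had ratios from 0.476 to 0.552. Cdk8 went from 3578 to 1994 CPM, with a UMI in 96.4% of vehicle and 99.8% of beta-elemene monocytes, and the origin of its reads was not examined here either. A pair of named genes rested on single cells. Acp5 had a ratio of 3.86, but 1 beta-elemene cell held 434 of the 577 UMIs of that library, and the ratio was 1.02 without the highest cells and 0.780 with doublets kept. Anxa11os, which overlaps Anxa11, was at 0.335 and at 0.607 without them. With doublets kept Lyz1 was at 1.87, Bola1 at 1.41, Fgf13 at 1.00, Akap11 at 0.835, Il31ra at 0.829 and Dennd5b at 0.722, with free RNA subtracted Bola1 was at 4.49, and within the largest monocyte sub-cluster the hypoxia median was -0.19, the glycolysis median 0.04 and Ero1l 0.832. Lyz1 and Ly6c1 have near-identical neighbours whose reads can be shared.

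In T cells the medians of the G2 and M phase and regulatory T cell lists were lower with beta-elemene, and that of cytotoxic genes was close to 0. The G2 and M phase list had a median log2 ratio of -0.32, with 21 of 23 genes below a ratio of 1 and none past 1.5-fold, among them Hmgb2 at 0.792. The dividing CD8 sub-cluster was as common in both libraries, 28 of 581 T and natural killer cells in vehicle (4.82%) and 32 of 636 in beta-elemene (5.03%). The regulatory T cell list had a median of -0.26, with 1 of 12 genes lower, none higher and 11 neither. That gene was Foxp3, the defining transcription factor of regulatory T cells, at 0.546, and Ikzf2 was at 0.690 and Ctla4 at 0.838. Regulatory T cells numbered 76 of 581 T and natural killer cells in vehicle and 65 of 636 in beta-elemene, and natural killer cells 48 and 75. The regulatory T cell list was measured over all T cells, and Foxp3 and Ikzf2 were among the top genes of the regulatory sub-cluster. Whether the share of that sub-cluster accounts for the lower median was not tested. The compared T cells also held 3 unnamed sub-clusters, with 39 and 37, 17 and 58, and 19 and 1 cells in vehicle and beta-elemene, and Ptrh2 was among the top genes of the last. The cytotoxicity list had a median of -0.01, the checkpoint list -0.06 and the naive and memory list 0.05, all inside the random range. Ifng (chromosome 10, 118441046 to 118445892), the main T cell interferon, went from 169 to 69.9 CPM, a ratio of 0.413 (0.346 to 0.492). In vehicle 1 cell held 213 of its 412 UMIs, and without the highest cell of each library the ratio was 0.623 (0.497 to 0.778). Within the largest T cell sub-cluster, of CD8 type, it was 1.09. Cxcl10 was at 0.346, Lmo4 at 0.435, the glycolytic hexokinase Hk2 at 0.458, from 135 to 61.9 CPM, and Csnk2a2 at 0.508. Ntng2, Pak1, Arl5c, Tinf2, Nelfe, Ptrh2 and the kinase gene Ikbke had ratios from 0.412 to 0.513. On the higher side were Tbc1d10b at 2.32, Nebl at 2.31, Sap30 at 2.08, Dusp14 at 1.91, Serpinb1a at 1.90, the respiratory chain gene Sdhd at 1.88 and the mitochondrial prohibitin Phb at 1.76, with Pdcd7, Fam53b, Fbxo8, Ltb4r1 and Plcl1 from 1.75 to 1.82. Sdhd was at 1.24 within the largest sub-cluster, and Plcl1 at 1.10 as a mean over cells.

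Dendritic cells, 135 in vehicle and 136 in beta-elemene once mast cells, B cells, basophils, plasmacytoid and unnamed cells of the cluster were set aside, had a higher median of interferon gamma genes and a lower one of proliferation genes. The interferon-induced GTPase Iigp1 went from 15.2 to 77.0 CPM, a ratio of 5.07 (3.0 to 9.08), and Cxcl9 from 68.7 to 151 CPM, a ratio of 2.19. Unc119 was at 2.35, Cd300c2 at 2.29 and the transcription factor Hhex at 2.17. Top2a, which untangles DNA in dividing cells, was lower at 0.355, as were the vascular co-receptor Nrp2 at 0.382, Chd3 at 0.366, Spata7 at 0.412 and Brd1 at 0.433. Top2a had 94 UMIs in vehicle and 36 in beta-elemene, though the shares of cells with a UMI were close, at 11.9% and 10.3%. The G2 and M phase list had a median of -0.51, with 3 of 7 genes lower, none higher and 4 neither. The Trem2 and Spp1 list, of lipid-laden macrophages, had a median of -0.35, with 4 of 9 lower, 1 higher and 4 neither, among them Fabp5 at 0.845 and Lgals3 at 1.56, though its summed counts had a log2 ratio of 0.07. Chemokines had a median of 0.35, with 3 of 13 higher, none lower and 10 neither, and Ccl17 and Ccl5 stood at 0.939 and 1.03. The dissociation and heat-shock list had a median of 0.41, with 5 of 18 higher, none lower and 13 neither, among them Hspa1b at 2.16, or 1.27 as a mean over cells, Junb at 1.09 and Hspa8 at 1.03. The chemokine median was -0.02 with at least 200 UMIs per gene and -0.37 in the largest sub-cluster, where the stress median was 0.00, Fabp5 0.355, Ccl17 0.620 and Junb 0.811. With free RNA subtracted Iigp1 was at 8.75 and Top2a at 0.179.

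Fibroblasts had a higher median of cholesterol synthesis genes and lower medians of matrix and chemokine genes with beta-elemene. The extracellular matrix list had a median log2 ratio of -0.16, with 19 of 25 genes below a ratio of 1 and none past 1.5-fold, among them tenascin, Tnc, at 0.696, the collagen Col3a1 at 0.895 and Sparc at 0.981. Chemokines had a median of -0.24, with 5 of 24 lower, 1 higher and 18 neither, including Ccl6 at 0.361 and Cxcl14 at 0.844, while Ccl2 was at 1.07. Cxcl5 went from 86.1 to 31.2 CPM, a ratio of 0.363 (0.325 to 0.404). The collagenase Mmp13 (chromosome 9, 7272514 to 7283331) went from 36.8 to 3.76 CPM, a ratio of 0.102 (0.0759 to 0.135), but 1 vehicle cell held 245 of the 519 vehicle UMIs, and the ratio was 0.158 without the highest cells and 0.242 with doublets kept. Mmp13 was at 0.294 with 10 CPM added to both libraries and at 0.0030 with free RNA subtracted. The neurotrophic factor Gdnf was at 0.294, and Sbspon, Pde4c, Ppm1n, Gucy1a2, Col23a1, Acat3, Bahcc1 and Scg3 had ratios from 0.325 to 0.415. Bahcc1 was at 0.659 without its highest cells. Among higher genes Angptl1, an angiopoietin-like protein, was at 5.04 (3.41 to 7.66), from 2.20 to 11.1 CPM, and the metalloprotease Adamts19 at 2.94. The granzymes Gzmd and Gzme were at 3.04 and 2.27, and 1 beta-elemene cell held 215 of the 526 Gzmd UMIs of that library, with a ratio of 2.12 without the highest cells. The share of fibroblasts with a Gzme UMI was 10.3% in vehicle and 9.08% in beta-elemene. Natural killer cells were not among the compared classes, so the naming rule could not screen out free RNA from them. The retinoic acid carrier Crabp2 was at 2.25, the growth cone protein Gap43 at 2.33, the DNA repair enzyme Ung at 2.36, and Nek4, Lhx8, Espn, Ube2cbp and Acot2 from 1.93 to 2.10. Cholesterol synthesis had a median of 0.35, with 1 of 22 genes higher, Fdps at 1.63, none lower and 21 neither. The type I interferon list had 5 of 22 genes higher, 1 lower and 16 neither, and oxidative phosphorylation a median of 0.21, with 1 of 41 lower and 40 neither. Genes of epithelial-mesenchymal transition had a median of -0.10 with none of 22 past 1.5-fold, and -0.01 in summed counts, where chemokines stood at -0.09. Angiogenesis genes had a median of -0.14, with 2 of 17 higher, 1 lower and 14 neither, but a mean of 0.02, and the ratio of Esm1 was 2.59, or 0.371 without the highest cell of each library, 1 of which held 54 of the 59 beta-elemene UMIs. Esm1 was at 6.11 in the largest sub-cluster and at 1.21 with 10 CPM added. With 10 CPM added to both libraries, 21 of the 24 named fibroblast genes moved by over 1.5 times, Angptl1 to 1.73 and Gdnf to 0.740.

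Endothelial cells, 192 in vehicle and 189 in beta-elemene, showed the highest medians of the type I interferon and MHC class I lists. The named higher genes included the interferon-induced Parp9 at 2.25 (1.61 to 3.19), the DNA sensor gene Ifi204 at 2.15, the GTPase Igtp at 1.99 and Mospd2 at 1.99. In the type I interferon list Ifit1, which binds viral RNA, stood at 2.47 and at 1.64 with 10 CPM added to both libraries. Cxcl10, a T cell chemokine, was at 2.25 in summed counts and at 0.738 as a mean over cells. Fatty acid oxidation genes had a median log2 ratio of 0.31, with 15 of 18 above a ratio of 1 and none past 1.5-fold, among them Acads at 1.48 and Etfb at 1.25. Lower genes included the artery genes Gja4 at 0.508 and Sema3g at 0.466, the peptide neurotensin, Nts, at 0.466, the heat-shock gene Hspa1b at 0.520 and Csnk2a2 at 0.449. As means over cells Nts was at 0.704 and Gja4 at 0.775.

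The median of glycolysis genes was 0.30 in monocytes and 0.25 in neutrophils, with no gene past 1.5-fold in either, and stood at 0.12 in both malignant cells and macrophages, inside the random range there. Nuclear genes of oxidative phosphorylation had medians of 0.21 in fibroblasts, 0.16 in monocytes and 0.11 in malignant cells, where 28 of 41 genes were above a ratio of 1 and Atp5k was the 1 gene past 1.5-fold, at 0.596. In malignant cells Cox4i1 stood at 1.14 and Cox6c at 0.839, and the summed counts had a log2 ratio of 0.02. In fibroblasts the summed counts had 0.07, and the median centred by transcript length was 0.09, while the monocyte median was 0.02 with doublets kept and 0.08 under the stricter cell filter. Cholesterol synthesis had a higher median in malignant cells and fibroblasts and a median of -0.05 in macrophages. A further 5 metabolic lists lay inside the random range in all 8 classes. Medians of the tricarboxylic acid cycle ranged from -0.23 in neutrophils to 0.11 in fibroblasts, of the pentose phosphate pathway from -0.15 in dendritic cells to 0.24 in fibroblasts, of fatty acid synthesis from -0.21 in monocytes to 0.12 in fibroblasts, of glycerophospholipids from -0.10 in neutrophils to 0.09 in endothelial cells and of sphingolipids from -0.11 in dendritic cells to 0.02 in monocytes. The median log2 ratio of all genes lay between -0.02 and 0.06 in the 8 classes. Every list described lay outside the middle 99% of 10000 random lists of the same size and expression, a limit set after the values were seen, which 75 of 327 pairs of list and class met. Of these, the 52 described here had at least 20% of the level of the class where the list was highest.

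**Figure D4:**
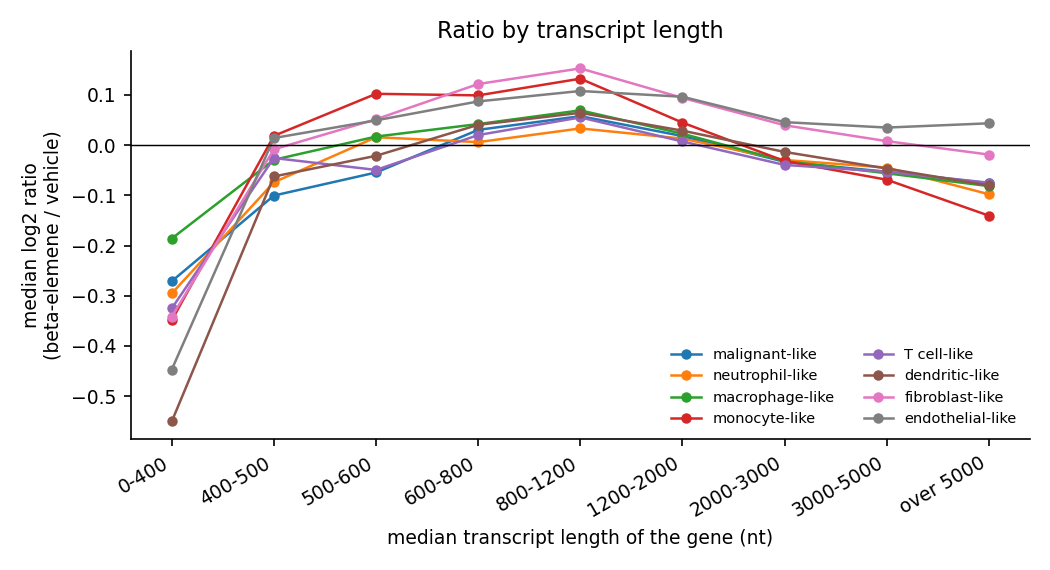
Median log2 ratio of beta-elemene over vehicle (vertical axis) by transcript length (horizontal axis, nt) with 1 line per cell class, 1 library per group. The shortest transcripts, up to 400 nt, have the lowest median in all 8 classes, from -0.55 in dendritic cells to -0.19 in macrophages.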

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

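Several named genes and described lists were higher in some classes and lower in others, and each is given here for that reason. The difference between classes was not tested. Arl5c, an Arf-like GTPase, had a ratio of 1.63 in macrophages and 0.478 in T cells. The CXCR3 ligand Cxcl10 had a ratio of 0.346 in T cells and 2.25 in endothelial cells, where it was 0.738 as a mean over cells, so that contrast depends on the summary. Cxcl5, a chemokine for neutrophils, had a ratio of 3.21 in malignant cells, from 3.05 to 9.80 CPM, and 0.363 in fibroblasts, from 86.1 to 31.2 CPM. The chemokine list had a median log2 ratio of -0.16 in macrophages, -0.24 in fibroblasts and 0.35 in dendritic cells. Within the largest sub-cluster it was 0.037 in macrophages and -0.37 in dendritic cells, and with at least 200 UMIs per member -0.025 in dendritic cells. The dissociation and heat-shock list had a median of -0.13 in malignant cells and 0.41 in dendritic cells, and 0.0020 in the largest dendritic sub-cluster.

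Of 3 patterns weighed with tests, the first was the higher neutrophil share with beta-elemene, and its tests were chosen after the result was seen. Among cells that were not malignant, neutrophils made up 17.9% in vehicle and 24.9% in beta-elemene, a ratio of 1.39 (1.3 to 1.49), while that of macrophages was 0.911 (0.877 to 0.947), so fewer malignant cells alone would not give the difference. Among cells thinned to 1000 UMIs the neutrophil difference was 5.76 points (4.83 to 6.68), so shallow barcodes near the minimum are not needed for it. More blood in the beta-elemene tumour is a candidate explanation left open. Barcodes with at least 100 haemoglobin UMIs numbered 7 and 15, a ratio of 2.10 (0.807 to 6.10). Red blood cells had been lysed before loading, so this count cannot measure how much blood a tumour held. With 1 library per group, an effect of the drug and a difference between mice or dissociations cannot be parted.

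The median of the MHC class I list was above 0 in all 8 classes, and the tests of this pattern were also chosen after the result was seen. Centred by transcript length, the lowest class median was still 0.19, which speaks against transcript length as the cause. Within the largest sub-cluster the lowest median of malignant cells, neutrophils, macrophages, monocytes and fibroblasts was 0.18. A change in the shares of sub-clusters alone would not give this remainder. A sub-cluster can itself hold several cell states, so the values do not settle how much a changed mix of states accounts for. Endothelial cells formed 1 sub-cluster and could not be tested. In T and dendritic cells the lowest such median was 0.16, which leaves the mix open there as well. Whole-library Ifng had a ratio of 0.837 (0.688 to 1.02) without the highest cell of each library and 0.572 with those cells. Ifng RNA at sampling does not settle whether interferon gamma had a part, and action before the sampling could not be examined.

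Genes with transcripts up to 400 nt had median log2 ratios from -0.55 to -0.19 in the 8 classes, and the tests of this pattern were chosen after the result was seen. Ribosomal protein genes with transcripts over 600 nt had a lowest class median of 0.035, above 0 in all 8 classes, so a lower level of ribosomal protein RNA as a group would not give it. The 6 ribosomal protein genes up to 400 nt had medians from -0.67 to -0.37. Other genes up to 400 nt, outside the ribosomal and respiratory families, had a highest class median of -0.063 and a lowest of -0.41, with 22 higher and 93 lower in malignant cells but 4 and 6 in endothelial cells and 6 and 8 in monocytes. In malignant cells these are 115 of the 127 genes that make the pattern, so the values largely restate it and leave its cause open, and ratios of genes with very short transcripts, Atp5k among them, are uncertain.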

How the results depend on the processing

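The values above rest on 1 library per group, so no alternative shows whether a difference exceeds the spread between mice, and the cause of a shift between settings was not tested. No paired analysis was possible because both libraries carry replicate number 1 with no pairing in the labels, and with 1 library on each side the results come from no test. Of the alternatives, those without low-depth clusters, without one-library clusters, centred by transcript length and without the cell with most UMIs were chosen after the values were seen, as were the largest sub-cluster for single genes, subtraction of free RNA for lists and the 99% limit. The rest were fixed before the data were examined.

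Among 8 class shares, 62 of 75 alternative differences lay inside the counting interval of the reported one, 12 lay outside it and 1 was reversed. A share or ratio was counted as reversed only if its interval had excluded no difference, and under that rule 7 shares were never reversed, though macrophage, dendritic and T and natural killer differences, whose intervals included 0, took both signs. In percentage points, the differences among immune cells alone were -0.730 for T and natural killer cells, -0.404 for dendritic cells, -6.33 for macrophages, 0.0477 for monocytes and 7.42 for neutrophils. With each library clustered alone they were 5.09 for macrophages and -3.85 for monocytes, the monocyte value being the 1 of opposite sign. At resolution 2.0 they were 0.183 for monocytes and 3.38 for neutrophils. From every deposited barcode the difference was -1.16 for macrophages. Without low-depth clusters they were -1.19 for macrophages and -6.06 for malignant cells, and without one-library clusters -6.12 for malignant cells. No monocyte value exists at resolution 0.5 and no dendritic value after thinning, because no cluster took those names.

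For the 52 described lists, 401 of 493 alternative values lay inside the counting interval, 81 lay outside it and 11 changed sign, and 43 lists kept their sign throughout. Within the largest sub-cluster the medians were, in malignant cells, 0.19 for MHC class I, -0.055 for Myc targets, 0.086 for cholesterol synthesis, -0.10 for stress genes, 4.66 for haemoglobin and -0.32 for interferon gamma (opposite sign). In neutrophils they were -0.11 for NF-kB, 0.18 for glycolysis, 0.39 for granule genes (opposite sign) and 0.052 for type I interferon. In macrophages these were 0.18 for MHC class I, 0.20 for MHC class II, 0.067 for angiogenesis (opposite sign), 0.037 for chemokines (opposite sign), -0.095 for epithelial-mesenchymal transition, 0.033 for interferon gamma, -0.22 for the M2-type list and 0.059 for the M1-type list. In monocytes the values were 0.50 for MHC class I, 0.040 for glycolysis, -0.19 for hypoxia (opposite sign) and 0.25 for oxidative phosphorylation. In dendritic cells they were -0.37 for chemokines (opposite sign) and 0.0020 for stress genes. In fibroblasts the value was 0.42 for cholesterol synthesis.

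As log2 ratios of summed counts the values were, in malignant cells, 0.33 for MHC class I, -0.039 for Myc targets, -0.073 for angiogenesis, 0.27 for cholesterol synthesis, 0.077 for hypoxia, 0.27 for interferon gamma and 0.021 for oxidative phosphorylation. In neutrophils they were 0.10 for NF-kB (opposite sign), 0.18 for glycolysis, -0.050 for granule genes and 0.39 for type I interferon. In macrophages these were 0.24 for MHC class I, -0.038 for chemokines and -0.29 for the M2-type list. In dendritic cells the values were 0.070 for the Trem2 and Spp1 list (opposite sign) and 0.28 for stress genes. In fibroblasts they were 0.17 for MHC class I, 0.058 for angiogenesis (opposite sign), -0.093 for chemokines, -0.0063 for epithelial-mesenchymal transition and 0.070 for oxidative phosphorylation.

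As means of members the values were, in malignant cells, 0.34 for MHC class I, -0.19 for stress genes, 0.062 for interferon gamma and 0.043 for oxidative phosphorylation. In neutrophils the value was 0.36 for type I interferon. In macrophages these were 0.24 for MHC class II, -0.20 for chemokines, -0.23 for epithelial-mesenchymal transition and 0.013 for the M1-type list. In monocytes the value was 0.23 for glycolysis. In fibroblasts they were 0.018 for angiogenesis (opposite sign), -0.14 for matrix genes and 0.13 for oxidative phosphorylation.

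With free RNA subtracted the median was, in neutrophils, -0.29 for NF-kB. In macrophages they were 0.24 for MHC class II, -0.0060 for epithelial-mesenchymal transition and -0.39 for the M2-type list. In dendritic cells these were -0.064 for the Trem2 and Spp1 list and 0.61 for stress genes. In fibroblasts the values were 0.43 for MHC class I, -0.20 for matrix genes and 0.24 for oxidative phosphorylation.

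Centred by transcript length the median was, in malignant cells, -0.13 for angiogenesis. In macrophages the value was 0.36 for MHC class I. In monocytes these were 0.22 for glycolysis and 0.10 for oxidative phosphorylation. In fibroblasts the values were -0.33 for chemokines, -0.16 for epithelial-mesenchymal transition, -0.19 for matrix genes and 0.093 for oxidative phosphorylation.

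With doublets kept the medians were, in monocytes, 0.17 for glycolysis, 0.062 for hypoxia, 0.024 for oxidative phosphorylation and 0.25 for type I interferon. In fibroblasts they were -0.16 for chemokines and -0.19 for matrix genes. With the median ratio scaled to 1 they were, in malignant cells, -0.11 for stress genes and 0.13 for oxidative phosphorylation. In fibroblasts they were -0.15 for epithelial-mesenchymal transition, -0.21 for matrix genes and 0.16 for oxidative phosphorylation. Under the stricter cell filter the median was, in malignant cells, 1.94 for haemoglobin. In monocytes the value was 0.085 for oxidative phosphorylation. In dendritic cells the value was -0.10 for the Trem2 and Spp1 list. Without low-depth clusters the median was, in malignant cells, 5.46 for haemoglobin. With at least 200 UMIs per member it was, in dendritic cells, -0.025 for chemokines (opposite sign). The G2 and M phase list of dendritic cells had too few members at 200 UMIs and in the largest sub-cluster, and endothelial cells formed 1 sub-cluster, so these have no such value.

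For 302 gene ratios, 2858 of 3367 alternative values lay inside the counting interval, 488 lay outside it and 21 were reversed, and 284 ratios were never reversed. The ratios reversed within the largest sub-cluster were Ldha in malignant cells at 0.925, Mif in malignant cells at 0.997, Cd274 in neutrophils at 0.982, Ifi27l2a in neutrophils at 0.891, Cxcl2 in macrophages at 1.03, Ero1l in monocytes at 0.832, Ldha in monocytes at 0.907, Ifng in T cells at 1.09 and Junb in dendritic cells at 0.811. Centred by transcript length they were Ldha in malignant cells at 0.993, Ctss in macrophages at 0.999, Cenpa in dendritic cells at 1.03 and Ccl2 in fibroblasts at 0.966. As means over cells they were Ldha in malignant cells at 0.980, Cxcl14 in fibroblasts at 1.04, Sparc in fibroblasts at 1.02 and Cxcl10 in endothelial cells at 0.738. With doublets kept they were Acp5 in monocytes at 0.780 and Cox8a in monocytes at 0.954, with free RNA subtracted Ctss in macrophages at 0.980, and without the cell with most UMIs Esm1 in fibroblasts at 0.371. Without being reversed, values lay outside the interval for 107 of 219 ratios in the largest sub-cluster, 86 of 302 with a pseudocount of 10 CPM, 74 of 302 as means over cells, 61 of 302 centred by length and 42 of 298 with free RNA subtracted. The counts were 38 of 299 with doublets kept, 29 of 302 with the median ratio scaled to 1, 20 of 300 under the stricter filter and 10 of 302 without the cell with most UMIs. They were 9 of 129 without low-depth clusters, 9 of 259 at resolution 0.5, 2 of 51 without one-library clusters, and 1 of 302 with mitochondrial, ribosomal, haemoglobin, S100a8 and S100a9 genes left out of the total. Settings that left a class's counts as they were gave no value for it.

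The UMI minimum cannot change a ratio, only which genes are named. With at least 500 UMIs the rule named 20 of the same 24 genes in malignant cells, 18 in macrophages, 4 each in monocytes and fibroblasts, 2 in neutrophils, 1 each in T cells and endothelial cells and 0 in dendritic cells. With at least 20 UMIs it named the same 24 in malignant cells, neutrophils and macrophages, 15 in fibroblasts, 10 in monocytes, 6 in T cells, 1 of 10 in dendritic cells and 0 of 10 in endothelial cells.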

Other observations

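The gene Csnk2a2, singled out after the values were seen, was named as lower in 3 classes, at 0.445 in malignant cells, 0.508 in T cells and 0.449 in endothelial cells. Genes named as lower in 2 classes were Il10 in malignant cells and neutrophils, Cdk8 and the zinc transporter Slc39a12 in macrophages and monocytes, Spata7 in monocytes and dendritic cells, Brd1 in neutrophils and dendritic cells, and Ntng2 in neutrophils and T cells. Named as higher in 2 classes were Cxcl9 in monocytes and dendritic cells, H2-T23 in malignant cells and macrophages, and Igtp in neutrophils and endothelial cells.

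Interferon gamma RNA came from few cells, chosen for a closer view after the values were seen. Of 581 vehicle T and natural killer cells 76 had an Ifng UMI, and of 636 beta-elemene cells 68 did. The 10 highest cells held 79.3% of its UMIs in vehicle and 55.0% in beta-elemene. In a CD8 sub-cluster of 67 and 75 cells Ifng went from 306 to 77 UMIs, and 1 vehicle T cell alone held 213. It went, in a dividing CD8 sub-cluster of 28 and 32 cells from 37 to 65, and in CD4 cells from 40 to 17. Gzmb, the granzyme that CD8 and natural killer cells use to kill, stood at 923 and 892 CPM in the largest CD8 sub-cluster, at 1181 and 1108 in the one with most Ifng, and at 458.0 and 506 in natural killer cells.

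Small populations inside the lymphoid and dendritic sets held few cells. The counting intervals of the shares of the named ones listed here overlapped, which does not show that the shares were equal. Those of B cells barely did, at 1.72% (0.357 to 4.96) of the dendritic cluster in vehicle and 8.38% (4.77 to 13.4) in beta-elemene. B cells numbered 3 in vehicle and 15 in beta-elemene, plasmacytoid dendritic cells 10 and 5, mast cells 14 and 8, or 21 and 15 where all mononuclear phagocytes were clustered together, and type 1 conventional dendritic cells 30 and 43. Mature dendritic cells numbered 37 and 29, gamma-delta T cells 17 and 11, and basophils 6 and 8. A cluster of 75 vehicle and 15 beta-elemene cells, with a median of 615 UMIs, and one of 17 and 44 cells that carried malignant and neutrophil markers were left without a name. For each of these clusters the counting intervals of its share of all cells did not overlap. Across whole libraries Malat1, a nuclear RNA, had a ratio of 0.840. Among all deposited barcodes, 7 in vehicle and 15 in beta-elemene held 96.3% and 96.9% of the haemoglobin UMIs.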
